A study of Arabidopsis thaliana with 24 samples.

How the data were processed

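Total RNA from rosette leaves of 2 Arabidopsis thaliana accessions, Tsu-1 and Kas-1, was labelled as biotinylated cRNA and hybridised to expression arrays. Plants grew singly in pots of porous ceramic medium under short days. Per the labels' protocols, dry pots were brought down stepwise by daily weighing until about 50% of their water remained on day 5, and wet pots were held near 90%. Leaves went into RNAlater and RNA was prepared with a Qiagen plant kit, per the labels' protocols. The 24 arrays form 4 groups of 6, and samples are named here by group and by the number in their titles (1 to 6 for dry, 7 to 12 for wet, in each accession).

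The series' design text names 3 biological replicates per combination, whereas its 24 arrays make 6 per combination. The labels do not say which arrays, if any, came from the same plant or the same RNA. Each array was therefore used as a sample, and the p-values measure the spread between arrays, part of which may be technical.

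The authors deposited 1 table of log2 expression values, with 1 value per locus and array for 20514 loci. The unit was read from the values, which ran from 3.12 to 14.2. The only tool in the submitters' processing notes is MAS5, with neither a version nor a role, so the background correction, the summary of probes per locus and the normalisation are not known. Array means lay between 6.87 and 6.94 and array medians between 6.77 and 6.87, so the deposited values had been scaled between arrays. The number of arrays limits the precision of every value. The table holds no control probe sets, so a planned test of RNA quality from the ends of control transcripts was not run.

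Loci were matched by their identifiers to the RefSeq gene table for TAIR10.1, which was used for names, gene lengths and the order of neighbouring genes. Of the loci, 20290 matched and 224 did not, and 8681 carried a symbol other than the locus name. No coordinates are given, because the build behind the array annotation is not stated.

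Loci with a mean log2 value above the 40th percentile (6.19) were tested, which left 12308. A model of the 4 group means was fitted to the deposited log2 values in R 4.3.3 with limma 3.58.1, with an intensity trend in the empirical Bayes step. From it came dry minus wet soil averaged over the accessions and within each accession, Tsu-1 minus Kas-1 averaged over the soils and within each soil, and the interaction. Two-sided p-values were adjusted by Benjamini and Hochberg within each comparison, and a locus was called at an adjusted p under 0.05. Adjusted p-values in the text are from limma unless another test is named.

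Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated from the data, adjusted over the lists of each comparison. The 24 lists hold 343 genes, of which 301 were in the table and 207 were tested. They cover drought and abscisic acid (ABA) responses, ABA core signalling, ABA metabolism, proline, aquaporins, light harvesting, the Calvin cycle, expansins and cell wall growth, cell division, glucosinolates, anthocyanins and flavonoids, salicylic acid defence, jasmonate response, heat shock, reactive oxygen scavenging, touch with wounding and handling, senescence, the circadian clock and flowering time. Others hold markers of guard cells and the stomatal lineage, vascular tissue, trichomes, roots and flowers.

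The comparisons, tests, lists, thresholds and the rule for named genes were fixed before the data were examined. The rule named the 10 called loci with the largest change in each direction for the averaged comparisons, and the 5 largest for those within 1 accession or soil. It required the higher group mean to exceed the median of the tested means (7.95). Where nothing was called, it took the 5 smallest p-values. Members of the fixed lists were also named.

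The procedure was tested on simulated data drawn for the 12308 loci with 200 changed by known amounts. For drying averaged over the accessions, 76.1% of changes of 0.5 on the log2 scale were recovered, as were 97.0% of changes of 1 and 100% of changes of 2. In that test 8 other loci were called. With real arrays shuffled, which keeps the correlation between loci, 65.7% of changes of 0.5 were recovered there, and 44.8% for drying in Tsu-1, where 21 other loci were called. For the interaction, 31.3%, 80.6% and 95.5% of changes of 0.5, 1 and 2 were recovered with independent noise, and 32.8%, 74.6% and 95.5% with arrays shuffled. Each value comes from a single draw. With 200 loci changed, the adjusted threshold is easier to pass than where few loci change. These shares may therefore be too high for the real drying and interaction comparisons.

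Shared variation within groups was summarised by principal components of the deviations of each array from its group mean over the tested loci. Loadings are given as the log2 change per SD of the array score.

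Other settings were quantile normalisation, median centring, no filter, a filter at the 60th percentile, array weights, no intensity trend, an adjusted p under 0.01, fits to the compared groups alone, same-numbered arrays as a fixed or a random block, arrays averaged in pairs to 3 per group, and each array left out. Further settings were chosen after seeing the data and are named with their values. Changes of pseudocount did not apply to log2 values. Masking probes that differ in sequence between the accessions was not possible, because the table holds no probe values.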

Results

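Expression of 20514 loci was measured in rosette leaves of the accessions Tsu-1 and Kas-1 after slow, mild soil drying or in wet soil. Each of the 4 combinations of accession and soil had 6 arrays. The values are log2 expression values as deposited, and 12308 loci above the intensity filter were tested. Array medians lay between 6.77 and 6.87. Correlations between arrays of 1 group across the tested loci ran from 0.907 to 0.995 in Kas-1 dry, 0.958 to 0.985 in Kas-1 wet, 0.945 to 0.985 in Tsu-1 dry and 0.872 to 0.983 in Tsu-1 wet. The labels name 3 biological replicates per combination for 6 arrays, so the errors below are between arrays.

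The first comparison, dry against wet soil averaged over both accessions, asked how leaves differed after mild drying. FSD1 (AT4G25100), an iron superoxide dismutase of the chloroplast, rose 8.16-fold, a log2 change of 3.03 (SE 0.58, adjusted p = 0.0370). Its mean was 6.64 ± 1.79 in wet and 9.83 ± 0.70 in dry Kas-1, and 5.77 ± 1.42 in wet and 8.64 ± 1.88 in dry Tsu-1 (SD, n = 6 arrays each), and 12 of 12 dry arrays lay above the median of the wet arrays, 8 of them above all wet arrays. LTP4 (AT5G59310), a lipid transfer protein, rose by 1.92 (SE 0.39, adjusted p = 0.0426), and LOX2 (AT3G45140), the chloroplast lipoxygenase of jasmonate synthesis, rose by 1.01 (SE 0.18, adjusted p = 0.0333). The catalase gene CAT2 (AT4G35090) rose by 0.68 (SE 0.13, adjusted p = 0.0333). COR15B (AT2G42530), which encodes a cold-regulated protein of the chloroplast stroma, fell by 0.73 on the log2 scale (SE 0.10, adjusted p = 0.00427), and 12 of 12 wet arrays lay above the median of the dry arrays, 6 of them above all dry arrays.

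In all, 16 of 12308 loci changed on drying, 10 up and 6 down, a balance that other settings turned to 60 up and 141 down (axis score as a covariate) or 15 up and 19 down (handling score), both chosen after seeing the data. The axis score comes from the deviations of these same arrays from their group means. As a covariate it leaves every log2 change as it was and acts on the error alone. An unadjusted p under 0.05 was found for 1151 loci, where 615 would be expected by chance. The median absolute log2 change over the tested loci was 0.07. The other loci that the naming rule took were AT3G53980 (log2 change 1.35), AT1G06640 (0.54), AT2G37240 (0.34), UGP2, a UDP-glucose pyrophosphorylase gene (0.27), and AT3G16670 (-1.06). Among the called loci below the intensity needed for naming, GBF2, a bZIP transcription factor gene (-0.45), MGD2, a galactolipid synthase gene (-0.30), and EGY3 (0.45) were chosen after their values were seen.

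**Figure D1:**
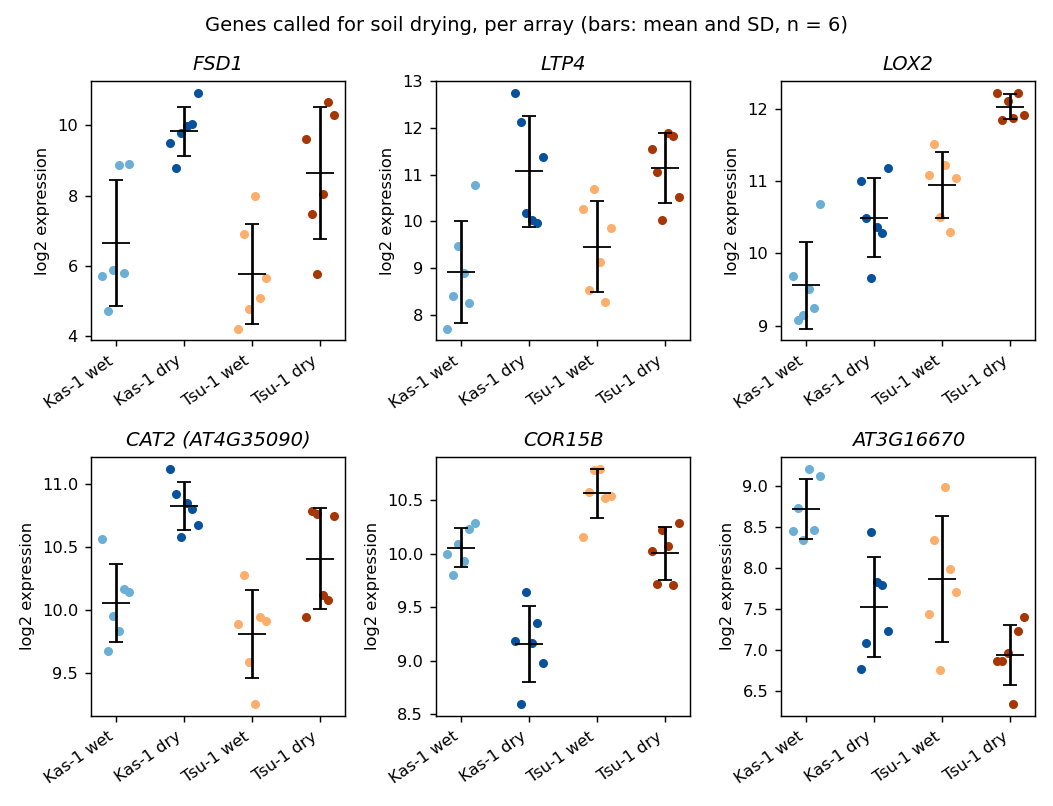
Log2 expression of 6 loci called between dry and wet soil (y axis) in each array of the 4 groups (x axis), with points for arrays and bars for the mean and SD of 6 arrays. FSD1 had means of 9.83 and 8.64 in dry Kas-1 and Tsu-1 against 6.64 and 5.77 in wet soil.

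Genes of the jasmonate list had positive changes in 9 of 9 tested members, with a median log2 change of 0.70. The list was called (camera adjusted p = 1.56e-05), but not at its own correlation between genes (adjusted p = 0.638 with an estimated correlation). Only LOX2 among its members was called over all genes, and 2 passed when adjusted over the list alone. Genes induced by touch, wounding and handling moved with them, with positive changes in 12 of 12 members and a median of 0.24 (adjusted p = 1.56e-05, and adjusted p = 0.638 with an estimated correlation). With the score of the handling list as a covariate, a setting chosen after seeing the data, the jasmonate mean was 0.16 against 0.56 without it. The jasmonate list lost its call (adjusted p = 0.328), while the drought and ABA list had a mean of -0.11 against 0.11 and was called (adjusted p = 0.0274). The score is each array's mean of the handling genes, which was itself higher in dry soil by 0.28 and in Tsu-1 by 0.47. As a covariate it can take up part of a change on drying or of an accession difference. None of those 12 handling genes was called by limma over all genes, and 2 passed when adjusted over the list alone. Of the 8 tested genes for scavenging of reactive oxygen, FSD1 and CAT2 rose, also when adjusted over the list alone, 3 had positive changes, and the list was not called (adjusted p = 0.172). The median of that list was -0.09 while its mean was 0.36.

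The drought and ABA list held 28 tested genes, of which LTP4 rose, COR15B fell and 26 were not called. Adjusted over the list alone, 1 rose and 2 fell. Its median log2 change was 0.06 and the list was not called (adjusted p = 0.655). RD29A, a dehydration-responsive gene, changed by -0.31 (adjusted p = 0.765), RD26 by 0.47 and NCED3, an enzyme gene of ABA synthesis from the ABA metabolism list, by 0.12, none of them called. The lists for ABA core signalling (adjusted p = 0.62), ABA metabolism (0.370) and proline (0.902) were not called either. Several members of these lists were not tested. P5CS1 and P5CS2 of the proline list and ABI2 of the core list were absent from the data. HAI1, HAI2 and HAI3 of the core list lay below the filter, as did RD29B, RAB18, HB-12, LEA4-5, ABF3 and GolS1 of the drought and ABA list. The results say nothing of those genes. In the ABA metabolism list BGLU18, a glucosidase gene that releases ABA from its conjugate, had a log2 change of 1.65 (SE 0.45, adjusted p = 0.154), and 1 gene rose when adjusted over the list alone. In the expansin and cell wall growth list, 3 of 20 members had positive changes and the median was -0.17 (adjusted p = 0.0610). Vascular markers had an adjusted p of 0.0805, senescence genes of 0.133, Calvin cycle genes of 0.176, guard cell markers of 0.215 and flavonoid genes of 0.336. For light harvesting it was 0.445, and for salicylic acid defence, heat shock and the clock it was 0.502 each. For cell division, flowering time, aquaporins and glucosinolates it was 0.641, 0.828, 0.852 and 0.852. Markers of trichomes, roots and flowers had 2, 7 and 8 genes in the table and 0 above the filter, so they were not tested.

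The number of loci called on drying ranged from 2, without Kas-1 dry 2 or Kas-1 wet 9, to 25, without Tsu-1 wet 12, when 1 array at a time was left out, and it was 102 with array weights (42 up and 60 down) and 5 or 6 with arrays averaged to 3 per group. COR15B kept its call without any of the 24 arrays in turn, whereas FSD1 kept it in 14, CAT2 in 13 and LTP4 in 7 of those 24 fits. Under 13 other settings, some chosen after seeing the data, COR15B was called in 12, FSD1 and CAT2 in 10 each and LTP4 in 9. COR15B lost its call (adjusted p = 0.0505) with consecutive numbers averaged to 3 per group, where 5 loci rose and 0 fell.

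The second question was whether each accession responded on its own. In Tsu-1, 1 locus changed, AT4G33550, which rose by 2.44 (SE 0.39, adjusted p = 0.0311) from 5.89 ± 0.36 to 8.32 ± 1.35 (SD, n = 6), with 6 of 6 dry arrays above all wet arrays. In Kas-1 its change was 0.38 (adjusted p = 0.773), and the difference between the accessions, 2.05, had an adjusted p of 0.460. Its Kas-1 mean in wet soil (5.19) lay below the lower quartile of all loci (5.21). That level is taken here as one where signal cannot be told from background, as the data hold no detection calls. The Kas-1 change and the difference between the accessions are therefore differences of array signal and set no exact transcript fold. In Kas-1, 9 loci fell and 0 rose in limma's test, and 1311 had an unadjusted p under 0.05, against 591 in Tsu-1. The Kas-1 count was 0 when the near-identical Kas-1 dry 4 and 5 counted as 1 array or when only the compared arrays were fitted, and array weights gave 280 higher and 723 lower. The Tsu-1 count was also 0 when only the compared arrays were fitted, with the change of AT4G33550 still 2.44 (SE 0.50, adjusted p = 0.560). COR15B fell by 0.90 on the log2 scale (SE 0.15, adjusted p = 0.0343). AT4G30650 fell by 0.65, AT1G13930 by 0.62, OEP16-1, a channel gene of the chloroplast envelope, by 0.55 (adjusted p = 0.0447 each) and NPH3, a gene of blue-light phototropism, by 0.47 (adjusted p = 0.0493). For each of these 5, the 6 wet arrays lay above the 6 dry arrays. The 4 others called, chosen here after their values were seen, were HXK1, a hexokinase gene (-0.35), PFK7, a phosphofructokinase gene (-0.45), GA2, a gibberellin synthesis gene (-0.62), and AT1G62330 (-0.59).

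Jasmonate genes had positive changes in 9 of 9 members in each accession, with list adjusted p-values of 0.00821 in Tsu-1 and 7.58e-04 in Kas-1 (adjusted p = 0.621 and adjusted p = 0.550 with an estimated correlation). With the handling score as a covariate, which can take up part of the drying change, both calls ended. The means were 0.22 against 0.53 without it in Tsu-1 (adjusted p = 0.322) and 0.10 against 0.59 in Kas-1 (adjusted p = 0.618). Array weights also ended the Kas-1 call (adjusted p = 0.179). Touch, wounding and handling genes had positive changes in 10 of 12 members in Tsu-1 (adjusted p = 0.0344, and adjusted p = 0.819 with an estimated correlation) and in 11 of 12 in Kas-1 (adjusted p = 1.5e-04, and adjusted p = 0.550 with an estimated correlation). In Tsu-1, light harvesting genes had positive changes in 8 of 8 members with a median of 0.10 (adjusted p = 0.0220, and adjusted p = 0.621 with an estimated correlation). Salicylic acid defence genes in Tsu-1 had positive changes in 1 of 11 members with a median of -0.22 (adjusted p = 0.0270, and adjusted p = 0.680 with an estimated correlation). Senescence genes in Kas-1 had positive changes in 7 of 7 members with a median of 0.40 (adjusted p = 0.0230, and adjusted p = 0.550 with an estimated correlation). Array weights ended the senescence call (mean 0.18 against 0.32, adjusted p = 0.337), as did the handling score (mean 0.15, adjusted p = 0.618). Quantile normalisation ended the calls of light harvesting (mean 0.06 against 0.10, adjusted p = 0.122) and handling (mean 0.21 against 0.22, adjusted p = 0.0573) in Tsu-1. There, light harvesting also lost its call with array weights (mean 0.03, adjusted p = 0.338) and handling with the 60th percentile filter (mean 0.15, adjusted p = 0.2495). Salicylic acid defence in Tsu-1 lost it with no filter (mean -0.18 against -0.26, adjusted p = 0.0510). Without Kas-1 dry 1 and 2 and Tsu-1 wet 7 and 9, the 4 arrays with a weight under 0.5, a setting chosen after seeing the data, the light harvesting mean in Tsu-1 turned to -0.03, salicylic acid defence in Tsu-1 and the handling, jasmonate and senescence lists in Kas-1 lost their calls, and the drought and ABA list in Tsu-1 was called with a mean of 0.52 (adjusted p = 1.54e-05). Those 4 arrays all had high scores on the axis of variation within groups (0.216 to 0.406), while Tsu-1 wet 8 and 10 at its low end (-0.352 and -0.349) were kept. Dropping only high arrays raises the Tsu-1 change of loci with positive loadings, among them 22 of 28 drought and ABA genes, and lowers their Kas-1 change. The direction of these moves follows in part from that choice. That setting called 45 loci in Tsu-1 and 106 in Kas-1 (36 higher and 70 lower), array weights called 17 and 1003, and leaving out single arrays gave 0 to 7 in Tsu-1 and 0 to 18 in Kas-1. In the main fit the drought and ABA list was called in neither accession, with means of 0.14 in Tsu-1 (camera adjusted p = 0.669) and 0.07 in Kas-1 (adjusted p = 0.848). Array weights, under which the same 4 arrays counted least, also called that list in Tsu-1 (mean 0.31, adjusted p = 0.00891). With the handling score it was called in Kas-1 with a mean of -0.19 (adjusted p = 0.0348).

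The interaction asked whether drying acted differently in the accessions. No locus was called by limma, with 722 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0689. The smallest p-values belonged to AT1G53035 (difference in response, Tsu-1 minus Kas-1, 1.12, SE 0.20, adjusted p = 0.0689), AT5G48960 (1.07), NPH3 (0.69), AT5G27950 (0.66) and HTA7, a histone H2A gene (0.60). The mean of AT1G53035 was 8.30 in dry and 7.79 in wet Tsu-1, and 7.55 in dry and 8.17 in wet Kas-1. No gene list was called, and light harvesting and salicylic acid defence had the smallest adjusted p (0.0667 each). Across loci, which are not independent replicates, the log2 responses of the accessions had a Pearson correlation of 0.233 and a Spearman correlation of 0.161, and 54.7% had the same sign. The Pearson correlation had a jackknife SE of 0.247 over the arrays, which is larger than the correlation itself. Without the 4 arrays of low weight that correlation was -0.169 and 353 loci were called for the interaction. Those arrays were dry in Kas-1 and wet in Tsu-1 and all high on the axis of variation within groups. Leaving them out therefore moves the accessions' responses opposite ways along that axis. With array weights, which count the same arrays least, the correlation was 0.0424 and 42 loci were called.

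The third comparison, Tsu-1 against Kas-1, asked how leaves of the accessions differ. FLC (AT5G10140), the MADS-box repressor of flowering, was 43.6-fold lower in Tsu-1, a log2 difference of -5.45 (SE 0.19, adjusted p = 1.63e-16). Its means were 10.60 ± 0.38 in wet and 10.18 ± 0.86 in dry Kas-1, and 4.88 ± 0.22 in wet and 5.01 ± 0.21 in dry Tsu-1 (SD, n = 6). PNP-A, which encodes a natriuretic peptide, was 24.9-fold lower (-4.64, SE 0.30), AOP2, a gene for making alkenyl glucosinolates, 11.1-fold lower (-3.48, SE 0.13), and BGL2 (PR2), a pathogen-induced glucanase gene, 8.48-fold lower (-3.08, SE 0.23). CRK4, a cysteine-rich receptor kinase gene, was 9.90-fold higher in Tsu-1 (3.31, SE 0.10, adjusted p = 2.6e-17), and PAP3, a purple acid phosphatase gene, 6.2-fold higher (2.63, SE 0.14). For each of these, the 12 arrays of one accession lay above the 12 of the other.

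Averaged over the soils, 5875 of 12308 loci (47.7%) differed, 2865 higher and 3010 lower in Tsu-1, and 367 of them by more than 2-fold. The median absolute log2 difference was 0.20. The accessions' 12 arrays each did not overlap for 518 loci, where chance gives 7.4e-05% of loci. The other loci that the naming rule took, which passes over dimmer loci with differences as large, were lower in Tsu-1 at ECS1 (-4.65), AT4G29200 (-4.63), LTP2, a lipid transfer protein gene (-3.66), AT2G32160 (-3.60), AT1G73490 (-3.58) and AT5G55450 (-3.40). They were higher in Tsu-1 at AT1G50290 (3.72), AT4G21640 (3.15), AT1G27030 (3.00), AT2G29290 (2.99), AT4G20480 (2.50), SEN1 (AT4G35770), a gene induced in darkness (2.43), AT1G70270 (2.36) and BT4 (2.35). Among the loci named for this comparison, the Tsu-1 means of FLC, PNP-A and AT4G29200 averaged over the soils lay below the lower quartile of all loci (5.21), a level taken here as one where signal cannot be told from background. Their folds here and within each soil are of signal and set no exact transcript fold. In dry and wet soil, Kas-1 means of AT1G50290 (5.34 and 5.21) and AT4G21640 (5.29 and 5.33) and Tsu-1 means of AT2G32160 (5.35 and 5.42) lay close to that level. The same caution holds for them. These values cannot separate a transcript difference from a sequence difference under an array probe. Each of the 20 loci kept its call under every setting it was measured in and without any of the 24 arrays in turn.

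**Figure D2:**
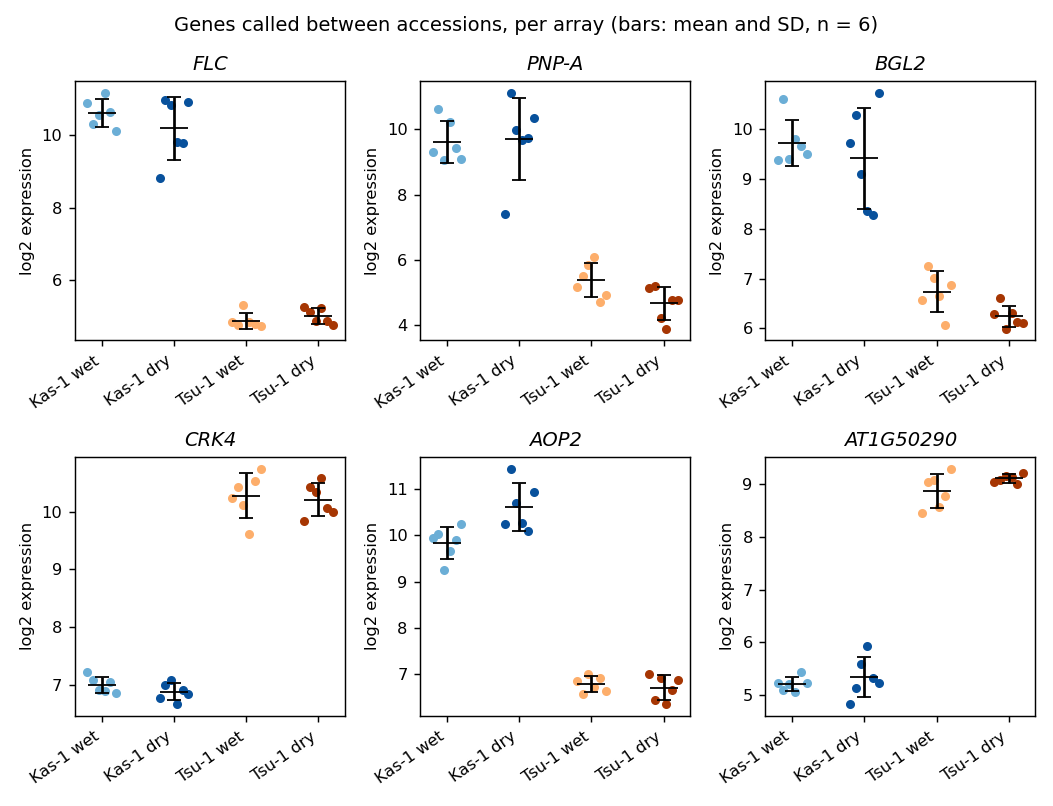
Log2 expression of 6 loci called between the accessions (y axis) in each array of the 4 groups (x axis), with points for arrays and bars for the mean and SD of 6 arrays. FLC had means of 10.60 and 10.18 in wet and dry Kas-1 against 4.88 and 5.01 in Tsu-1.

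Salicylic acid defence genes were lower in Tsu-1, with 8 of 11 members lower, 1 higher and a median of -0.74 (adjusted p = 0.00414, and adjusted p = 0.425 with an estimated correlation). PR1 was lower by a log2 difference of -2.67 (SE 0.37), WRKY54 of -1.86, PR5 of -1.62 and WRKY70 of -1.24, while CBP60G, a regulator of salicylic acid synthesis, was higher (1.0). Drought and ABA-responsive genes were higher in Tsu-1, with 14 of 28 members higher, 0 lower by limma's test and a median of 0.62 (adjusted p = 0.00414, and adjusted p = 0.559 with an estimated correlation). RD29A was higher by 2.12 (SE 0.25), COR413IM1 by 1.86, XERO2 by 1.46 and COR15A by 1.01. Genes of the touch, wounding and handling list, which also holds CBF1, CBF2 and CBF3, were also higher, in 6 of 12 members (adjusted p = 0.0414, and adjusted p = 0.695 with an estimated correlation), with CBF3 at 1.43 (SE 0.19), ERF5 at 0.85 and CBF2 at 0.79. The list's name is a label for its members, and whether handling itself differed was not tested. ABA core signalling had 8 higher and 2 lower of 16 members (adjusted p = 0.0338, and adjusted p = 0.425 with an estimated correlation), among them the kinase genes SNRK2.2 (1.04), OST1 (0.90) and SNRK2.3 (0.88) and the receptor gene PYL6 (-0.89). Adjusted over the list alone, the counts were 8 lower and 1 higher for salicylic acid defence, 14 higher for drought and ABA, 6 higher for handling, and 9 higher and 2 lower for ABA core signalling.

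Cell division genes were lower in Tsu-1 in 5 of 6 members, with a median of -0.82 (adjusted p = 0.0127, and adjusted p = 0.425 with an estimated correlation). They included TSO2 (-1.18) and RNR1 (-1.02), subunit genes of ribonucleotide reductase, and PCNA1, a replication clamp gene (-1.05). Clock genes were higher in 6 of 7 members, with a median of 0.34 (adjusted p = 0.0127, and adjusted p = 0.425 with an estimated correlation), among them ELF4 (0.84) and PRR5 (0.60). Vascular markers were higher in 5 of 6 members (adjusted p = 0.00894, and adjusted p = 0.425 with an estimated correlation), with the sucrose transporter gene SUC2 at 0.74 and the proton pump gene AHA3 at 0.67. Guard cell markers were 1 higher and 3 lower of 4 (adjusted p = 0.526). The counts for cell division, clock, vascular and guard cell genes were the same adjusted over the list alone. With the score of the handling list as a covariate, a setting chosen after seeing the data, the drought and ABA mean fell from 0.59 to 0.24. That list lost its call (adjusted p = 0.137), as did ABA core signalling (adjusted p = 0.0822). The score was itself higher in Tsu-1 and includes CBF2 and CBF3, which were higher there, so it can take up part of the accession difference. With a filter at the 60th percentile, salicylic acid defence, cell division, ABA core signalling and handling lost their calls (adjusted p = 0.0920 each). Their means were then -0.84, -0.83, 0.26 and 0.38, against -1.01, -0.79, 0.27 and 0.47 in the main fit. Handling also lost its call without the 4 arrays of low weight (mean 0.37, adjusted p = 0.0899).

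The other lists were not called, although single members differed. In the flowering time list SOC1, a promoter of flowering, was higher by 1.92 (SE 0.27) and SVP by 0.38, and FLC was lower (list adjusted p = 0.809, median 0.07, mean -0.85). Among glucosinolate genes 6 were higher and 2 lower of 21, with AOP2 lower and FMO GS-OX1 higher by 1.09 (adjusted p = 0.428). Their median was 0.19 and their mean was -0.02. In the reactive oxygen list the copper and zinc superoxide dismutase genes CSD2 (-0.88) and CSD1 (-0.68), their copper chaperone CCS (-0.55) and CAT2 (-0.33) were lower of 8 tested (adjusted p = 0.105). CSD2 lay between 10.02 and 11.36 in Tsu-1 dry 3 and 6 and wet 11 and 12, arrays singled out after their values were seen, and between 11.86 and 12.59 in the other 8 Tsu-1 arrays, against 11.92 to 12.89 in Kas-1. In the same order, CSD1 ran from 10.69 to 11.51, 12.06 to 12.91 and 12.2 to 12.9, and CCS from 9.21 to 10.22, 10.29 to 10.91 and 10.46 to 11.02. Flavonoid genes were lower in 3 of 5, with FLS1 at -1.23 and CHS at -0.82 (adjusted p = 0.0648). Aquaporins were 6 higher and 1 lower of 12, with PIP1;1 at 0.60 (adjusted p = 0.0638). LOX2 was higher by 1.46, and the jasmonate list had 2 higher and 1 lower of 9 (adjusted p = 0.345). Expansin and cell wall genes were 4 higher and 7 lower of 20 (adjusted p = 0.50). ABA metabolism, with NCED3 higher by 0.98, had an adjusted p of 0.390, proline, with ERD5 higher by 1.11, of 0.599, and senescence of 0.259. Light harvesting, with 0 of 8 called by limma, had an adjusted p of 0.704, the Calvin cycle of 0.526 and heat shock of 0.840. Adjusted over the list alone, 7 aquaporins were higher, 4 ABA metabolism genes were higher, and the jasmonate list had 2 higher and 0 lower.

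Within wet soil 3703 loci differed between the accessions, 1624 higher and 2079 lower in Tsu-1, and within dry soil 3757, 2064 higher and 1693 lower. Both soils called 2419 loci, 2415 of them in the same direction (1196 higher and 1219 lower), where independent lists would share 272 and 286. Across loci, the differences in wet and in dry soil had a Pearson correlation of 0.873 and a Spearman correlation of 0.825. FLC differed by -5.72 in wet and -5.17 in dry soil, and PNP-A by -4.24 and -5.04. AOP2 was among the 5 lowest in dry soil (-3.91). AT1G47400 was higher in Tsu-1 in wet soil by 3.17 (SE 0.56, adjusted p = 2.08e-04), with means of 9.07 ± 1.15 in wet Tsu-1, 6.70 ± 1.26 in dry Tsu-1 and 5.89 ± 0.73 in wet Kas-1 (SD, n = 6). AT4G33550 was higher in Tsu-1 in dry soil by 2.75 (SE 0.39, adjusted p = 1.78e-05).

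Arrays of the same group also differed from each other along a shared axis, which held 46.9% of the variance within groups against 8.91% for the next. Among the 15 loci with the highest loadings were NAC019, a stress-induced transcription factor gene (1.2 log2 units per SD of the score), HSP70 (1.05), JAZ7 (0.95), a jasmonate-induced repressor gene, and RD26 (0.84). At the other end were GER3, a germin-like protein gene (-1.06), FSD1 (-0.95) and XTH8, a cell wall enzyme gene (-0.94). The median loading was 0.52 for jasmonate genes, 0.34 for senescence genes, 0.33 for drought and ABA genes (22 of 28 positive) and 0.29 for handling genes (12 of 12 positive). It was -0.35 for cell division genes and -0.31 for expansins and cell wall growth (1 of 20 positive). Across loci, loadings had a correlation of 0.216 with the drying change and of 0.414 with the accession difference. Kas-1 dry 1 and 2 and Tsu-1 wet 7 and 9, the 4 arrays of low weight, lay at the upper end, with scores of 0.216, 0.406, 0.353 and 0.394.

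**Figure D3:**
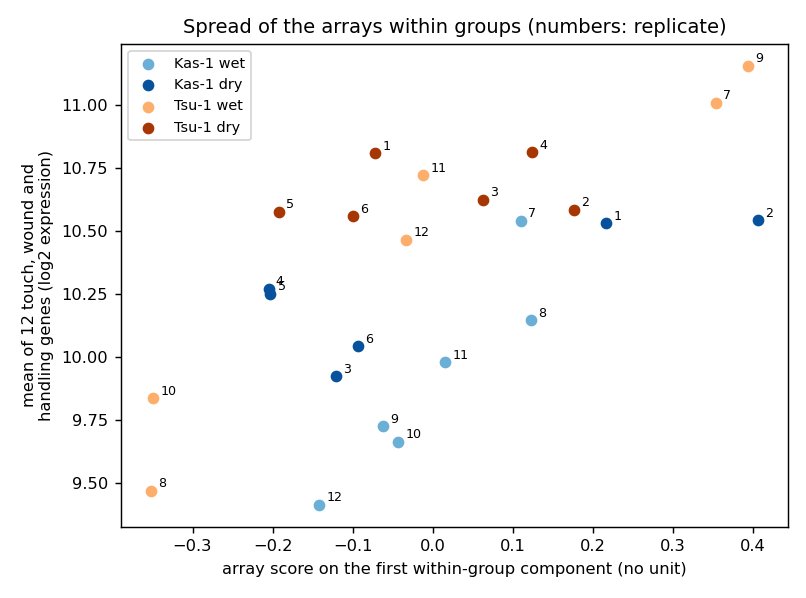
Score of each array on the shared axis of variation within groups (x axis, no unit) against its mean log2 expression of the 12 touch, wounding and handling genes (y axis), with a point per array coloured by group and numbered by replicate. Tsu-1 wet 9 had a score of 0.394 and a handling mean of 11.15, against -0.352 and 9.47 in Tsu-1 wet 8.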

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

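The tests of harvest time of day, of low-oxygen genes and of probe mismatches below, the handling score as a covariate and Kas-1 dry 4 and 5 as 1 array were chosen only after the result was seen. In groups of 6 arrays, 9 of 244 sets of values had an array far from the others, where chance gives about 12. Each is given with the gap to the nearest array as a share of the whole range, which lay past the 95% critical value of Dixon.

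UGP2 in Tsu-1 dry 5 was 8.41 against 8.50 to 8.53 in the others (share 0.762). AT1G70270 in Tsu-1 dry 4 was 6.72 against 8.01 to 8.71 (0.645). FLC in Tsu-1 wet 9 was 5.31 against 4.73 to 4.86 (0.792). BGL2 in Kas-1 wet 8 was 10.60 against 9.38 to 9.81 (0.649). AT1G47400 in Kas-1 dry 1 was 7.51 against 4.78 to 5.73 (0.651). The mean of the reactive oxygen list was 11.46 in Kas-1 dry 6 against 11.09 to 11.21 (0.678), and 10.06 in Tsu-1 dry 3 against 10.71 to 11.05 (0.659). The guard cell mean in Tsu-1 dry 4 was 6.26 against 6.62 to 6.71 (0.803). The vascular mean in Tsu-1 wet 7 was 8.93 against 8.65 to 8.72 (0.746).

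The shared axis of variation within groups had loadings that correlated at 0.818 across loci between Tsu-1 and Kas-1. Array-wide intensity stays open, because the deposited values had been scaled between arrays, so that the Pearson correlation of -0.184 between scores and array medians (permutation p = 0.332, rho -0.289, and -0.277 without the 2 farthest arrays) decides nothing. Harvest time of day stays open, since the mean absolute loading of 7 clock genes lay at percentile 24.3 of random lists, inside their spread, all 7 loaded in the same direction and CCA1, LHY and RVE8 were below the filter. A length-dependent loss of RNA stays open, because the rank correlation of loading and gene length was 0.101, just past its bound of 0.1. A stress around harvest that differed between plants is a candidate explanation, formed on the same arrays. Of 23 low-oxygen genes 13 were tested, and 12 of these had positive loadings. Their median was 0.48, at percentile 100 of random lists, and at percentile 100 again without the members among the top loadings. The random lists were matched for expression and not for co-regulation, so another co-regulated list could reach this too. Jasmonate genes had a median loading of 0.52. The result therefore singles out neither low oxygen nor the time of harvest.

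FSD1 is known to rise when copper is short, when CSD1, CSD2 and CCS fall. Lower copper supply in dry soil could not be decided, since the mean correlation of FSD1 with these genes within groups was 0.156 with a jackknife SE of 0.253, and their changes on drying were -0.24, -0.32 and -0.23, none called. Of genes expected to rise with low copper, COPT1 changed by -0.05, COPT2 by 0.09, ZIP2 by 0.03, FRO3 by -0.43 and CCH by 0.44, none called, and their correlations with FSD1 ran from -0.648 to 0.175, which goes mostly against it. The tables argue against the shared axis as the whole cause by direction only. With the handling score as a covariate the jasmonate mean moved from 0.56 to 0.16, while the change of FSD1 grew to 3.66 (SE 0.49, adjusted p = 0.00194) from 3.03 (SE 0.58). FSD1 loads on the axis at -0.95, against the handling genes. The prediction for another cause, a move smaller than the SE, was not met, since the growth exceeds the SE of 0.58. The handling score only stands in for the axis, whose own score cannot move a log2 change. A response of FSD1 to drying itself stays open and was not tested further.

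Neighbouring loci differed the same way between the accessions slightly more often than in shuffled orders. Among 1789 neighbouring pairs of called loci, 52.9% had the same direction, against a median of 50.1% and a 99th percentile of 52.8% in 1000 shuffles, a small excess that local sequence or copy number differences, or probes shared by tandem copies, may produce. Loci differing by over 2-fold made 21 neighbouring pairs where random choices gave a median of 7, and 71.4% of these had the same direction, below the shuffled 99th percentile of 76.2%. Among them LUL1 (1.37), DIP2 (1.13), AT5G03230 (1.02) and UBQ3 (1.22) made a run, AT1G23120 (-2.17) and AT1G23130 (1.62) went opposite ways, and AT1G34040 and AT1G34060 had the same value (1.77), as probes shared by both would give. Mismatches between an accession's sequence and the probes stay open, since 0.165% of the loci called in both soils had opposite directions, which a mismatch and a stable transcript difference would both give, and a regulatory difference, not tested, stays open as well.

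Regrouping the compared arrays in 100 ways, the real grouping included, gave as many called loci as the real 16 for drying in 1 of them, with a highest other count of 1, so chance can be excluded there as far as the 6 arrays of a group are independent, with real counts of 10 with Kas-1 dry 4 and 5 as 1 array and 5 or 6 with arrays averaged to 3 per group. With the same limit, it can be excluded for the accessions averaged over soils (real 5875, 1 of 100, highest other 1), in wet soil (real 3703, 1 of 100, highest other 2884) and in dry soil (real 3757, 1 of 100, highest other 2907). For drying in Kas-1 the share is under 0.05 (real 9, 2 of 100), but 1 other grouping called 26, and the real count was 0 with Kas-1 dry 4 and 5 as 1 array or with the compared arrays alone. Chance cannot be excluded for drying in Tsu-1 (real 1, 7 of 100, highest other 835). For the interaction the real count was 0, so 100 of 100 groupings had to give as many and nothing follows from it (highest other 936). Groupings that call far more loci than the real one point to a structure among the arrays. In Tsu-1 wet, arrays 8 and 10, 7 and 9, and 11 and 12 lay in close pairs. Averaging to 3 per group joined 11 and 12 in 1 setting and never the other pairs, so it does not test this pairing. The independence that these exclusions need is therefore in doubt there.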

How the results depend on the processing

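The settings without 4 arrays, with Kas-1 dry 4 and 5 as 1 array, and with an axis or handling score as a covariate were chosen only after the result was seen. Among 801 values for named genes under other settings, 717 kept their direction and side of the threshold, 64 lost the call, 20 gained one and 0 reversed. For gene lists the counts were 178, 22, 2 and 1 of 205, and the 2 others moved. With 1 array left out, 1251 of 1464 gene values and 431 of 456 list values stayed. Of those gene values, 204 lost the call. These 204 and the 64 above were all changes on drying, whereas every named difference between the accessions kept its call. Signal over background limits the dimmer loci, which were left untested.

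Counts of called loci that moved are given as drying averaged, drying in Tsu-1 and drying in Kas-1, with others named, and the cause was not tested unless the setting shows it. Median centring gave 1 in Kas-1. No filter gave 10, 2 and 1. A 60th percentile filter gave 10 averaged, 0 in Tsu-1 and 2 for the interaction. Array weights gave 102 (42 up, 60 down), 17 and 1003 (280 up, 723 down), and 42 for the interaction. An adjusted p under 0.01 gave 1, 0 and 0, and 1906 and 2031 for the accessions in wet and dry soil, as a stricter threshold must. Fits to the compared groups alone gave 0 in Tsu-1 and 0 in Kas-1. Averaging consecutive numbers gave 5, 2 and 0, and numbers 3 apart 6, 0 and 0, with fewer samples.

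Without Kas-1 dry 1 and 2 and Tsu-1 wet 7 and 9, drying called 45 in Tsu-1 and 106 in Kas-1, the interaction 353, the correlation of responses reversed to -0.169 and the light harvesting mean in Tsu-1 to -0.0283. These arrays were all high on the axis of variation within groups, so the choice itself pushes the responses of the accessions apart. Kas-1 dry 4 and 5 as 1 gave 10 averaged and 0 in Kas-1. The axis score as a covariate gave 201 (60 up, 141 down), 23 and 260, and 31 for the interaction, through a smaller error and with every log2 change as in the main fit. The handling score, itself higher in dry soil and in Tsu-1, gave 34 averaged, 20 in Tsu-1, 2385 for the accessions in wet soil and 4 for the interaction.

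Leaving out 1 array gave 2 to 25 averaged, 0 to 7 in Tsu-1, 0 to 18 in Kas-1, 0 to 3 for the interaction, 5521 to 6173 for the accessions averaged, 2873 to 4257 in wet and 2971 to 4097 in dry soil, and correlations of 0.0810 to 0.299. Drying averaged called 2 without Kas-1 dry 2 or wet 9, 3 without Kas-1 dry 1, dry 6 or wet 11 or Tsu-1 dry 1 or 3, 4 without Kas-1 wet 10, 5 without Kas-1 wet 12 or Tsu-1 wet 7 or 10, 7 without Tsu-1 wet 11, 9 without Kas-1 wet 8 or Tsu-1 dry 5, and 25 without Tsu-1 wet 12. In Tsu-1 it called 3 without Tsu-1 dry 2, 3 or 6, 6 without wet 9, 7 without wet 7, and 0 without Kas-1 dry 3, Kas-1 wet 7 to 12, or Tsu-1 dry 1, 4, 5 or wet 8, 10, 11, 12. In Kas-1 it called 0 without Kas-1 dry 4, wet 7, 9, 10, 11, 12 or Tsu-1 dry 1, 1 without Kas-1 dry 5 or Tsu-1 dry 3, 5, 6, 2 without Kas-1 dry 1, 3 without dry 2, 4 without dry 3 or 6, and 18 without wet 8. The interaction called 1 without Kas-1 dry 6 or wet 8, 2 without Kas-1 dry 1 or Tsu-1 dry 2, and 3 without Tsu-1 dry 6.

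Arrays of the 2 accessions share numbers, but the labels do not say that a number marks a pair. Correlations of same-numbered arrays ran from -0.397 to 0.555, with 4 of 12 over 0.1. With the number as a fixed replicate block, the accessions differed at 5661 loci averaged, 3392 in wet and 3454 in dry soil, and 0 were called for the interaction. Dry and wet arrays share no number, so drying was fitted with a random replicate block, which gave 15, 1 and 8.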

Other observations

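The genes and arrays in this part were chosen after their values were seen, as were the tests of their relations. Copper and zinc superoxide dismutase genes varied among Tsu-1 arrays of both soils. CSD2 ran from 10.02 to 12.59 in Tsu-1 and from 11.92 to 12.89 in Kas-1. It was 10.02 in Tsu-1 dry 3, 10.66 in dry 6, 11.36 in wet 11 and 10.43 in wet 12. CSD1 lay between 10.69 and 11.51 in those arrays, and CCS was 9.21, 9.24, 10.22 and 9.43. FSD1 there was 5.76, 10.29, 5.07 and 5.64.

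Other genes were picked after seeing that they moved opposite to CSD2. NAS3, a nicotianamine synthase gene for metal transport, was 9.12, 8.60, 7.47 and 9.11 in them and 6.36 to 7.29 in the other Tsu-1 arrays. HMA2, a zinc-exporting ATPase gene, was 9.07, 9.07, 8.39 and 8.60 against 6.93 to 7.70. CYP79B3, a gene of indole glucosinolate synthesis, was 9.12, 9.28, 8.22 and 8.93 against 7.46 to 8.27, so wet 11 lay inside the range of the others there. In Kas-1 these genes ran from 6.45 to 8.23, 7.24 to 8.46 and 7.29 to 8.35.

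Over deviations from group means in the 24 arrays, 8 relations with CSD2 were computed, adjusted over these 8. Their p-values do not count the choice of the genes from all loci, so they are no independent evidence. The permutations also take each array as a separate unit, while Tsu-1 wet 11 and 12, both low in CSD2, were a close pair (SD of the difference 0.288). These p-values may therefore be too small for that reason as well. The Pearson r was -0.889 for NAS3 (permutation p = 1e-04, rho -0.814, permutation p = 4e-04, adjusted p = 2e-04) and -0.769 without the 2 farthest arrays. For HMA2 it was -0.860 (permutation p = 5e-05, rho -0.833, permutation p = 1e-04, adjusted p = 1e-04) and -0.822 without them. For CYP79B3 it was -0.879 (permutation p = 1e-05, rho -0.850, permutation p = 1e-05, the smallest these permutations can give, adjusted p = 8e-05) and -0.834 without them. For CCS it was 0.943 (permutation p = 3e-05, rho 0.899, permutation p = 1e-04, adjusted p = 1e-04) and 0.892 without them. The r was 0.858 for CSD1, -0.828 for CYP79B2, -0.734 for NAS4 and -0.680 for OPT4, with adjusted p-values up to 0.005. Within Tsu-1 and within Kas-1 it was -0.915 and -0.807 for NAS3, -0.933 and -0.356 for HMA2, -0.960 and -0.604 for CYP79B3, and 0.909 and -0.0430 for CSD1. Leaving out 2 arrays keeps 2 of the 4 Tsu-1 arrays with the lowest CSD2.

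Kas-1 dry 4 and 5 were the closest of all pairs of arrays in a group, with a correlation of 0.995 and an SD of the difference of 0.147, where the next pair had 0.243. Within Tsu-1 wet, the SD was 0.264 for 8 and 10, 0.277 for 7 and 9 and 0.288 for 11 and 12. The next pair there, 8 and 12, had 0.386. Whether such pairs share a plant or an RNA is not known.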
